A study of Mus musculus with 60 samples.

How the data were processed

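RNA-seq was measured in 36 libraries of mouse ES cells and ChIP-seq in 24, all 60 samples of the series, with 2 libraries per group. The series sets out to compare the transcriptome and the binding of KLF4 and P53 between WT and Lnc956-deficient ES cells under DNA damage. Per the labels the cells grew in DMEM/F12 with 20% serum replacement and LIF, the P53 antibody was against P53 phosphorylated at serine 15 and came from CST, and the KLF4 antibody came from R&D. The first RNA-seq set and the ChIP samples were treated with 10 uM etoposide. The treated KLF4 ChIP samples are labelled 3 h. For the first set and the P53 ChIP samples the time is not given in the sources used here. In the time course most labels say 1 uM, but 4 libraries in 4 groups say 10 uM, each beside a replicate at 1 uM, and an alternative left these 4 out. Columns of the time-course table were matched to labels by their names, and those of the combined-loss cells by elimination. A further 4 columns of that table, named as WT at 0 h and 3 h, belong to no labelled sample and were not used.

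The deposited expression tables hold FPKM (fragments scaled by transcript length and by mapped fragments), 1 column per library. Per the submitters' processing notes reads were aligned with TopHat2 2.0.8 and quantified with Cufflinks and Cuffdiff 2.1.1 on mm10, and ChIP reads were aligned with Bowtie2 2.1.0. Peaks were called with MACS2 2.2.7.1. The scaling between libraries, the gene annotation and the cutoff of the peak calls are not given in the sources used here. The smallest -log10 q in every peak list lay just over 2 (from 2.002 to 2.318). The deposited peak lists give, per peak, the fold enrichment over the control as a ratio, the -log10 p and the -log10 q, with a pileup height. The depth of each library is unknown, since no file gives read counts, so no interval for counting error was computed. Replicates of the peak lists were called separately.

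The first set's table had 24883 rows. Of 280 symbols that stood on several rows, 140 with identical rows were kept once and 140 with different rows were left out, which left 24206 symbols. The time-course table had 24314 rows. A gene was tested when it reached 1 FPKM in at least 2 libraries, which kept 12733 and 14223 genes, of which 12694 and 14174 have a position in the reference annotation. Values were analysed as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, with all groups of a set in 1 model, moderated variances with a trend and adjusted p by Benjamini-Hochberg (threshold 0.05) within each comparison. Folds are therefore on the scale of log2(FPKM + 1), and levels are group means in FPKM. The 18 comparisons across genes were the 5 of the first set and the 13 of the time course given in the report. A difference of responses was tested as an interaction contrast. The labels give no further information on batches.

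For gene groups, 16 lists with 274 genes were written before the data were seen: P53 targets, naive, general, and formative and primed pluripotency, 2-cell-like, trophectoderm, endoderm, mesoderm and primitive streak, neural ectoderm, immediate early, interferon response, G1/S and replication, G2/M, DNA repair, fibroblast and feeder genes, and mitochondrial genes for RNA quality, which are not analysed here. The 2-cell list was tested in the time course only, since too few of its members passed the filter in the first set. Lists were tested with camera in limma with a preset correlation of 0.01 and again with an estimated one. Over the 18 comparisons 87 calls of lists passed with the preset correlation and 7 with an estimated one, namely fibroblast genes in both treatment comparisons of the first set, naive genes in knockout cells from 0 h to 9 h, and P53 targets, naive, general pluripotency and G2/M genes in combined-loss cells from 0 h to 9 h. Where the report writes adjusted p after a list, it is camera's, adjusted over the lists of that comparison.

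Genes to name were fixed by rule before the data were seen. For each comparison they were up to 10 that rose most and 10 that fell most among genes past the threshold with a group mean of 1 FPKM or more in 1 of the groups and no overlap between libraries of the groups, from each list up to 4 members with the smallest p (up to 2 where none passed), and Trp53, Klf4, Pou5f1, Nanog, Sox2, Esrrb, Zfp42, Cdkn1a, Mdm2 and Ccng1. Named peaks were the 3 of highest fold per group within 10 kb of a gene and the sites of highest fold at those genes. Y-linked genes and Actb were chosen after their values were seen. A list of 26 genes induced in low oxygen was drawn up after Ndrg1, Bnip3 and Adm had been seen, from genes not named before and before the list was tested. A gene listed at 0 in a group is given no fold.

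Peaks were joined with bedtools 2.31.1, and a site of a group is a peak seen in both of its libraries, with an overlap of 1 bp or more. Sites were assigned to every gene within 10 kb of its body. Peak numbers were compared on the log2 scale with exact two-sided permutation tests (within cell line for treatment, 36 arrangements for P53 and 1296 for KLF4, and 70 splits of 4 against 4 treated libraries), and genes near sites against other tested genes with Fisher's exact test. Because pileup over background differed between libraries, peaks were also counted after pileups were thinned to a common background. Further work used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

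The procedure was tested on simulated libraries, drawn from the fitted group means and variances of the real tables, with changes planted in 200 genes. They follow the model that was fitted, so the rates below do not cover batch or cell differences between libraries. For knockdown against WT under etoposide 98% of planted log2 changes of 1 were recovered and 100% of those of 2, with 5.3% of calls false. For knockout against WT at 9 h 87% and 99% were recovered, with 2.1% false. Alternatives planned before the data were seen were a replicate block, a fit with only the groups compared, a pseudocount of 0.1, no filter on low values, leaving out each library, a minimum log2 change of 1, quantile scaling, leaving out the 10 uM libraries, a minimum mean of 10 FPKM, an estimated correlation, peaks with a fold or a -log10 q of at least 5, a window of 50 kb, sites within 2 kb of gene starts, overlap by 50% of the peak, the WT sites for all cell lines, and the top 2000 sites. Alternatives added after seeing the data were thinned pileups, 2 kb of either gene end, leaving out the knockout and P53 knockdown libraries of 0 h and 3 h, 6 h as the reference of the 9 h response, and a block with crossed replicate numbers. Lnc956 itself and the RNA of the rescue lines are not analysed here.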

Results

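The data were collected from mouse embryonic stem (ES) cells that had or lacked Lnc956, a long noncoding RNA, with and without etoposide, a topoisomerase II inhibitor that leaves double-strand breaks in DNA. A first RNA-seq set held 4 groups: wild-type (WT) and Lnc956 knockdown cells, untreated or treated. A time course held 14 groups: WT cells at 6 h and 9 h, and Lnc956 knockout cells, P53 knockdown cells and cells with both losses (combined-loss cells) at 0 h, 3 h, 6 h and 9 h of etoposide. ChIP-seq peak lists covered P53 in 4 groups (WT and Lnc956 knockdown, untreated or treated) and KLF4 in 8 groups (WT, Lnc956 knockout, knockout rescued with full-length Lnc956 and knockout rescued with Lnc956 lacking bases 862-1253, untreated or treated). Each group held 2 libraries. The depth of the libraries is unknown, since the files give FPKM values and peak lists without counts. Between 11568 and 12031 genes reached 1 FPKM in a library of the first set, and between 11245 and 12858 in a library of the time course. The labels do not say that replicates were separate cultures, so each p measures only the spread between these libraries, which may be technical.

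The first comparison asked how WT ES cells respond to etoposide. Transcripts of the P53 pathway rose and those of naive pluripotency fell. Mdm2, which encodes the ligase that limits P53, rose from 65.8 ± 1.36 to 150 ± 0.776 FPKM (SD, n = 2; log2 change 1.18 ± 0.04 SE, adjusted p = 6.00e-08), and Btg2, an antiproliferative P53 target, from 37.3 to 149 FPKM. Plk2 rose from 32.0 to 125 FPKM and Ccng1 from 103 to 161 FPKM, while Cdkn1a, the P53-induced inhibitor of cyclin-dependent kinases, fell from 177 to 151 FPKM. Nanog, a core factor of the pluripotency network (mm10, 6:122707489-122714633), fell from 173 ± 3.36 to 50.2 ± 2.88 FPKM (SD, n = 2; log2 change -1.77 ± 0.05 SE, adjusted p = 1.58e-08). Esrrb, a receptor that sustains naive cells, fell from 82.6 to 33.7 FPKM and Zfp42, a naive marker, from 222 to 128 FPKM. Pou5f1 rose from 1243 to 1455 FPKM, and Klf4, which encodes the factor profiled by ChIP, rose from 18.4 to 30.5 FPKM (log2 change 0.69 ± 0.08 SE). Trp53, which encodes P53, rose from 149 to 226 FPKM.

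Among genes that rose most in treated WT cells were Nkx2-9, a homeobox gene of the neural tube (1.83 to 51.8 FPKM), Trp73, a P53 relative (1.02 to 21.0 FPKM), and Fam83h (2.32 to 30.2 FPKM). The replication gene Mcm2 rose from 113 to 383 FPKM, the DNA repair gene Fancd2 from 15.7 to 48.4 FPKM and Myc, a growth factor-responsive oncogene, from 4.28 to 27.4 FPKM. Genes that fell most included Saa3, an acute-phase gene (684 to 9.35 FPKM), the chemokine gene Ccl11 (25.2 to 0.397 FPKM) and Ndrg1, induced by low oxygen (64.5 to 2.15 FPKM). In all, 9792 of 12733 genes passed (5001 higher, 4791 lower, and 4870 and 4976 after quantile scaling), of which 1977 changed at least 2-fold. Of 32 P53 targets, 27 rose and 2 fell (27 and 2 adjusted over the list alone, median log2 change 0.64, camera adjusted p = 1.49e-06). Of 20 naive genes 4 rose and 14 fell (5 and 14 adjusted over the list alone, median log2 change -0.61, camera adjusted p = 0.044). These adjusted p were 0.136 and 0.476 with an estimated correlation. All 17 fibroblast and feeder genes fell, also when adjusted over the list alone (median log2 change -2.25, camera adjusted p = 4.82e-09), and this call held with an estimated correlation. Dcn, a collagen-binding proteoglycan of fibroblasts, stood at 92.3 FPKM in untreated and 5.59 FPKM in treated WT cells. The list's median level was 54.2 FPKM in untreated WT, 56.1 FPKM in untreated knockdown, 8.23 FPKM in treated WT and 7.91 FPKM in treated knockdown cells. The Y-linked Eif2s3y moved with treatment too, at 2.55, 2.41, 28.3 and 29.1 FPKM in the same order, so the treated libraries of either genotype differed from the untreated ones in both marker sets. The remaining lists did not pass in treated against untreated WT cells: 8 of 11 immediate early genes were higher, 8 of 11 interferon response genes lower, 10 of 19 G1/S and replication genes higher, and 9 of 25 DNA repair genes higher with 9 lower. The counts of higher and lower members were 6 and 7 of 15 general pluripotency, 6 and 9 of 17 G2/M, 3 and 7 of 13 formative and primed, 1 and 4 of 8 endoderm, 2 and 3 of 5 mesoderm, 3 and 2 of 5 neural and 0 and 4 of 7 trophectoderm genes.

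The second comparison asked for the same response in Lnc956 knockdown cells. P53 targets rose by less than in WT cells, and Nanog, Esrrb and Zfp42 fell by less. Naive genes did not pass as a list (7 higher and 11 lower of 20, the same adjusted over the list alone, camera adjusted p = 0.811). Mdm2 rose from 65.9 ± 0.005 to 76.9 ± 3.34 FPKM (SD, n = 2; log2 change 0.22 ± 0.04 SE, adjusted p = 0.00188), Btg2 from 36.8 to 110 FPKM, and Ccng1 was 105 FPKM before and 110 FPKM after (adjusted p = 0.251). Nanog fell from 153 ± 0.585 to 111 ± 2.22 FPKM (log2 change -0.46 ± 0.05 SE), Esrrb from 91.1 to 74.0 FPKM and Zfp42 from 300 to 272 FPKM. Among genes that rose most, Nr0b1, an orphan receptor of naive cells, went from 31.1 to 113 FPKM, the TGF-beta family gene Gdf3 from 17.3 to 106 FPKM and the stress cytokine gene Gdf15 from 11.5 to 56.8 FPKM. The G2/M genes Ube2c and Cdc20 rose from 220 to 380 and from 114 to 194 FPKM. In all, 8739 genes passed (4015 higher, 4724 lower), 1133 of them at least 2-fold. P53 targets were 19 higher and 8 lower (the same adjusted over the list alone, median log2 change 0.36, camera adjusted p = 0.00701), and G2/M genes 12 higher and 2 lower of 17 (12 and 3 adjusted over the list alone, camera adjusted p = 0.0377). G1/S genes were 10 higher and 2 lower of 19 (camera adjusted p = 0.0377), immediate early genes 7 higher and 3 lower of 11 (0.0434), and interferon response genes 2 higher and 8 lower of 11 (0.0377), with the same counts when adjusted over the list alone. These 5 adjusted p lay from 0.193 to 0.309 with an estimated correlation. Fibroblast genes were all lower (17 of 17, and 17 adjusted over the list alone, median log2 change -2.30, camera adjusted p = 1.88e-10), and that call held.

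The third comparison asked what Lnc956 knockdown changes without etoposide. Few genes changed by much, and those that fell most included Ndrg1 and Bnip3, which low oxygen induces. Ndrg1 fell from 64.5 to 14.4 FPKM (log2 change -2.25, adjusted p = 0.00341), Bnip3, a mitophagy receptor gene, from 196 to 60.6 FPKM, Adm, which encodes adrenomedullin, from 47.2 to 14.4 FPKM, and the glycolytic Aldoc from 22.7 to 5.25 FPKM. Ndufa4l2 fell from 127 to 30.6 FPKM and Ankrd37 from 31.7 to 9.23 FPKM. Chac1, a target of the amino acid stress response, rose from 5.35 to 13.2 FPKM and the chemokine gene Ccl2 from 79.6 to 159 FPKM. The naive marker Zfp42 rose from 222 to 300 FPKM (adjusted p = 0.00109) and Nanog fell from 173 to 153 FPKM (adjusted p = 0.0302), while Mdm2 was 65.8 FPKM in WT and 65.9 FPKM in knockdown cells (adjusted p = 0.972). In all, 3032 genes passed (1952 higher, 1080 lower), of which 89 changed at least 2-fold, 5 of them up and 84 down. No fixed list passed. The count rested on single libraries: it was 1119 without WT replicate 1, 1434 without WT replicate 2 and 869 without knockdown replicate 1.

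The fourth comparison, the main contrast of the first set, asked how treated knockdown cells differ from treated WT cells. Naive pluripotency genes stood higher and P53 targets lower in knockdown cells. Nanog was 111 ± 2.22 against 50.2 ± 2.88 FPKM in WT cells (SD, n = 2; log2 difference 1.14 ± 0.05 SE, adjusted p = 1.43e-06), Esrrb 74.0 against 33.7 FPKM, Zfp42 272 against 128 FPKM and Nr0b1 113 against 52.9 FPKM. Sox2 and Pou5f1 did not pass (adjusted p = 0.87 and 0.131). Mdm2 was 76.9 ± 3.34 against 150 ± 0.776 FPKM (SD, n = 2; log2 difference -0.96 ± 0.04 SE, adjusted p = 1.84e-06). The P53 targets Pmaip1, which encodes the death factor Noxa (17 against 43.5 FPKM), Apaf1, which encodes the apoptosome scaffold (10.4 against 20.6 FPKM), and Trp53inp1 (50.6 against 89.2 FPKM) were lower too, while Cdkn1a was 148 against 151 FPKM (adjusted p = 0.607). The transcript of Trp53 itself was 252 against 226 FPKM (adjusted p = 0.0386), and that of Klf4 33.0 against 30.5 FPKM (adjusted p = 0.304). The Polycomb cofactor gene Jarid2 stood at 45.5 against 14.2 FPKM, Bmp4, a signal of mesoderm patterning, at 18.8 against 4.35 FPKM, and the mitotic kinase gene Plk1 at 70.6 against 30.3 FPKM. The Nodal antagonist Lefty1 was 3.78 against 23.2 FPKM and Parp10 0.972 against 8.99 FPKM.

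Between treated knockdown and WT cells 5810 genes passed (2896 higher, 2914 lower, and 3141 and 2640 after quantile scaling), 441 of them at least 2-fold (82 higher, 359 lower). Naive genes were 15 higher and none lower of 20 (16 higher adjusted over the list alone, median log2 difference 0.40, camera adjusted p = 2.83e-07), general pluripotency genes 10 higher of 15 (10 adjusted over the list alone, camera adjusted p = 4.66e-04) and formative genes 7 higher of 13 (7 and 1 lower adjusted over the list alone, camera adjusted p = 0.0319). G2/M genes were 12 higher and 1 lower of 17 (the same adjusted over the list alone, camera adjusted p = 3.82e-05), and P53 targets 2 higher and 20 lower of 32 (the same adjusted over the list alone, median log2 difference -0.42, camera adjusted p = 2.07e-06). With an estimated correlation none of these 5 passed (adjusted p from 0.0867 to 0.345). Fibroblast levels (7.91 against 8.23 FPKM) and Eif2s3y (29.1 against 28.3 FPKM) were alike in these groups, but Ddx3y (8.67 against 6.25 FPKM) and the median of the Y-linked genes (6.06 against 4.16 FPKM) were higher in knockdown cells. The authors gave a list of 1007 genes for this contrast, of which 829 were tested and 825 passed (178 higher, 647 lower), but the list was chosen on these samples and is not independent evidence.

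The fifth comparison asked whether the etoposide response itself differed between knockdown and WT cells. The response of naive genes was higher and that of P53 targets lower in knockdown cells. The response of Nanog differed by 1.31 ± 0.07 SE on the log2 scale (n = 2, limma adjusted p = 2.03e-05), that of Esrrb by 0.97 and that of Zfp42 by 0.65. That of Mdm2 differed by -0.96 ± 0.06 SE (n = 2, limma adjusted p = 4.21e-05), that of Ccng1 by -0.59, that of Apaf1 by -1.19 and that of Dcxr, a sugar reductase gene with P53 sites, by -1.27. Jarid2 (1.79), the G2/M kinase gene Plk1 (1.22) and the pluripotency RNA-binding gene Lin28a (1.06) had higher responses in knockdown cells, Lefty1 a lower one (-2.51), and Klf4 did not pass (adjusted p = 0.299). In all, 4212 genes passed (1730 higher, 2482 lower), 443 of them with a difference of at least 2-fold. The share that was higher was 41.1%, against 51.4% after quantile scaling, so the excess of lower genes over all calls rests on the scaling. Among differences of at least 2-fold the excess of lower genes stayed, with 109 higher and 334 lower, and 164 and 260 after quantile scaling. Naive genes were 15 higher and 1 lower (the same adjusted over the list alone, camera adjusted p = 7.83e-07), general pluripotency genes 9 and 0 (11 and 0 adjusted over the list alone, 6.03e-05), G2/M genes 13 and 1 (14 and 1 adjusted over the list alone, 1.13e-06) and formative genes 8 and 0 (9 and 1 adjusted over the list alone, 6.03e-05). P53 targets were 3 higher and 19 lower (3 and 22 adjusted over the list alone, camera adjusted p = 2.18e-05). The adjusted p of these 5 lists lay from 0.0694 to 0.086 with an estimated correlation.

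**Figure D1:**
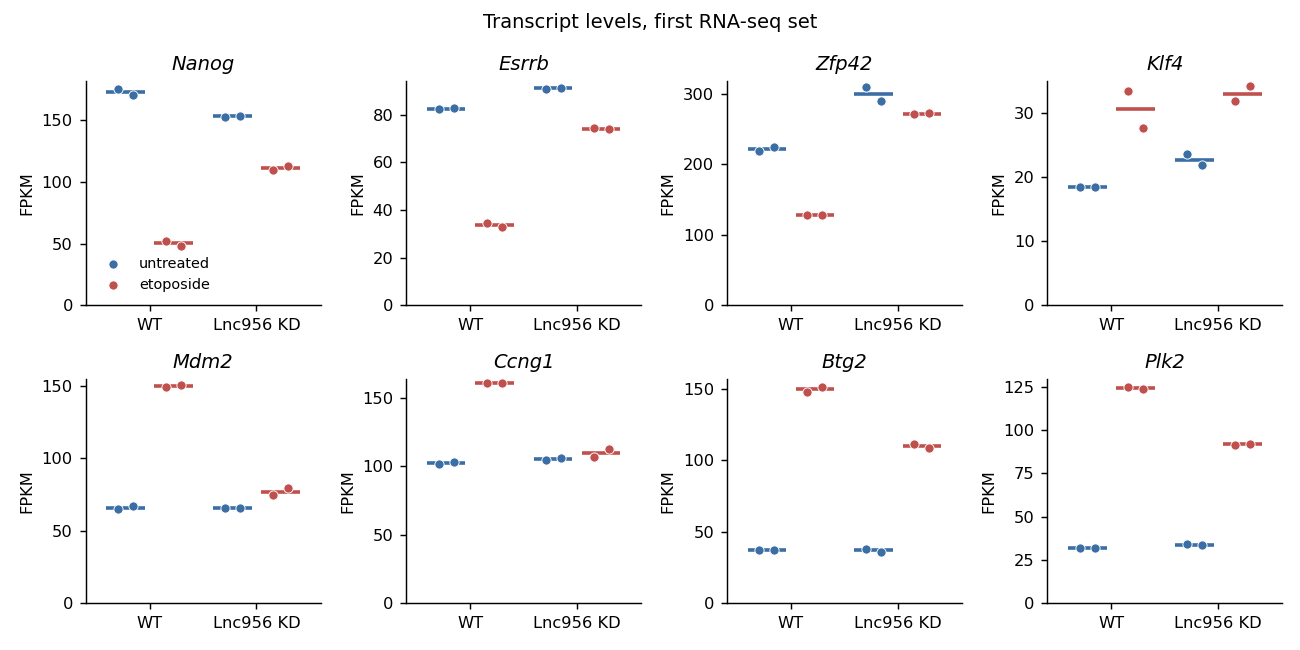
FPKM of named genes in the first RNA-seq set (vertical axis) by group (horizontal axis), with a point per library and a line at the mean of n = 2. Nanog, Esrrb and Zfp42 stood higher, and Mdm2 lower, in treated knockdown than in treated WT cells.

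The sixth and seventh comparisons asked how Lnc956 knockout cells differ from WT cells after 6 h and 9 h of etoposide. Nanog was higher and the P53 target Mdm2 lower in knockout cells at both times, while the naive list went both ways at 6 h (8 higher and 4 lower of 20). At 6 h Nanog was 119 ± 2.69 FPKM in knockout and 52.7 ± 3.4 FPKM in WT cells (SD, n = 2; log2 difference 1.16 ± 0.10 SE, adjusted p = 1.65e-08), and Mdm2 132 ± 0.316 against 235 ± 2.94 FPKM (SD, n = 2; log2 difference -0.82 ± 0.10 SE, adjusted p = 1.83e-06). The P53 target Perp, a desmosome gene, was 67.3 against 229 FPKM, Gdf15 19.1 against 78.3 FPKM and Fas, a death receptor gene, 2.82 against 14.8 FPKM. Nr0b1 was 102 against 20.6 FPKM, Lin28a 58.2 against 6.36 FPKM and Dppa3, a germline and naive marker, 16.2 against 0.294 FPKM, whereas Esrrb did not pass (adjusted p = 0.144) and Zfp42 was 35.4 against 44.6 FPKM. At 9 h Nanog was 106 against 59.6 FPKM and Mdm2 129 against 191 FPKM, but Esrrb (18.9 against 38.1 FPKM), Zfp42 (29.4 against 74.8 FPKM), Sox2 (53.2 against 159 FPKM) and Klf4 (16.8 against 36.7 FPKM) were all lower. The G2/M genes Ube2c (104 against 291 FPKM) and Plk1 (15.6 against 30.0 FPKM) were lower at 9 h.

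The 6864 genes that passed at 6 h were 3106 higher and 3758 lower in knockout cells, and the 6269 at 9 h were 3334 higher and 2935 lower, with 2118 and 1730 changed at least 2-fold. After quantile scaling 3013 were higher and 3669 lower at 9 h. P53 targets were 1 higher and 21 lower of 32 at 6 h (the same adjusted over the list alone, camera adjusted p = 2.12e-05) and 1 higher and 10 lower at 9 h (the same adjusted over the list alone, 0.0116). At 9 h G2/M genes were 0 higher and 16 lower of 17 (17 lower adjusted over the list alone, 1.34e-06) and naive genes 4 higher and 11 lower of 20 (4 and 12 adjusted over the list alone, 0.0158). Formative genes were higher at 6 h (8 and 1 of 13, camera adjusted p = 2.49e-04) and at 9 h (9 and 2, 0.016). General pluripotency (9 and 3 of 15) and trophectoderm genes (7 and 1 of 9) were higher at 6 h (0.0248 for each), and endoderm genes at 9 h (6 and 1 of 10, 0.0158). DNA repair (2 and 11 of 25, 0.0188) and G1/S genes (1 and 8 of 19, 0.016) were lower at 9 h. Fibroblast genes were higher at 6 h (15 and 1 of 17, 2.25e-11) and 9 h (15 of 17, 2.76e-14). None of these passed with an estimated correlation (adjusted p from 0.13 to 0.446). Of these, Tagln, a smooth-muscle actin-binding gene, was 346 FPKM in knockout and 1.73 FPKM in WT cells at 6 h. The fibroblast list's median level was 16.1 and 23.1 FPKM in knockout against 0.221 and 0.258 FPKM in WT cells. Within the time course Actb, a cytoskeletal gene, ranged from 424 to 508 FPKM in WT libraries and from 898 to 2750 FPKM in all others. Eif2s3y was listed at 0 in WT and at 1.52 and 1.45 FPKM in knockout cells. The counts of knockout against WT cells may therefore in part measure such differences between the lines.

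The eighth and ninth comparisons set P53 knockdown against WT cells at 6 h and 9 h, which asks what P53 itself does under etoposide. Trp53 was 78.0 ± 0.355 against 221 ± 18.7 FPKM at 6 h (SD, n = 2; log2 difference -1.49 ± 0.10 SE, adjusted p = 1.27e-10) and 64.3 against 191 FPKM at 9 h. P53 targets were lower in knockdown cells, and so were genes of the 2-cell stage, the embryonic stage that rare ES cells resemble. Mdm2 was 97.8 against 235 FPKM at 6 h and 76.0 against 191 FPKM at 9 h, and Perp 62.1 against 229 FPKM at 6 h. Zscan4f, a telomere-associated gene of 2-cell-like cells, was 1.87 against 46.0 FPKM at 6 h and 2.18 against 56.5 FPKM at 9 h. Nanog was higher (188 against 52.7 FPKM at 6 h, 142 against 59.6 FPKM at 9 h) and so was Zfp42 (171 against 44.6 FPKM at 6 h), while Esrrb was lower (23.7 against 40.9 FPKM at 6 h). The interferon-regulated Isg15 was 12.4 against 0.059 FPKM and Bst2 192 against 77.6 FPKM at 9 h.

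In P53 knockdown against WT cells 7560 genes passed at 6 h (4105 higher, 3455 lower) and 7745 at 9 h (4220 higher, 3525 lower), with 2710 and 2686 changed at least 2-fold. Quantile scaling changed the log2 differences by -0.113 at 6 h and -0.119 at 9 h in the median over genes. It turned the share that was higher from 54.3% to 45.6% at 6 h (3587 higher, 4287 lower) and from 54.5% to 43.6% at 9 h. P53 targets were 1 higher and 20 lower of 32 at 6 h (1 and 22 adjusted over the list alone, camera adjusted p = 7.23e-06) and 1 higher and 19 lower at 9 h (the same adjusted over the list alone, 3.95e-05). All 16 genes of the 2-cell list were lower at both times, also adjusted over the list alone (median log2 difference -2.84 at 6 h, camera adjusted p = 2.29e-10, and 5.49e-10 at 9 h). Interferon genes were higher at 6 h (9 and 1 lower of 13, camera adjusted p = 0.0229) and 9 h (10 of 13, 0.012), as were trophectoderm genes at 6 h (8 and 1 of 9, 0.0164) and endoderm genes at 9 h (7 and 1 of 10, 0.0166). DNA repair (2 and 9, 0.0242), G1/S (0 and 10, 0.00974) and G2/M genes (0 and 8, 0.0326) were lower at 9 h. With an estimated correlation none passed (adjusted p from 0.0854 to 0.611). Fibroblast levels differed here as well, with a list median of 66.0 and 82.8 FPKM in P53 knockdown cells, and Eif2s3y stood at 4.49 and 5.33 FPKM there against 0 in WT cells. These counts, too, may in part measure such differences between the lines.

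**Figure D2:**
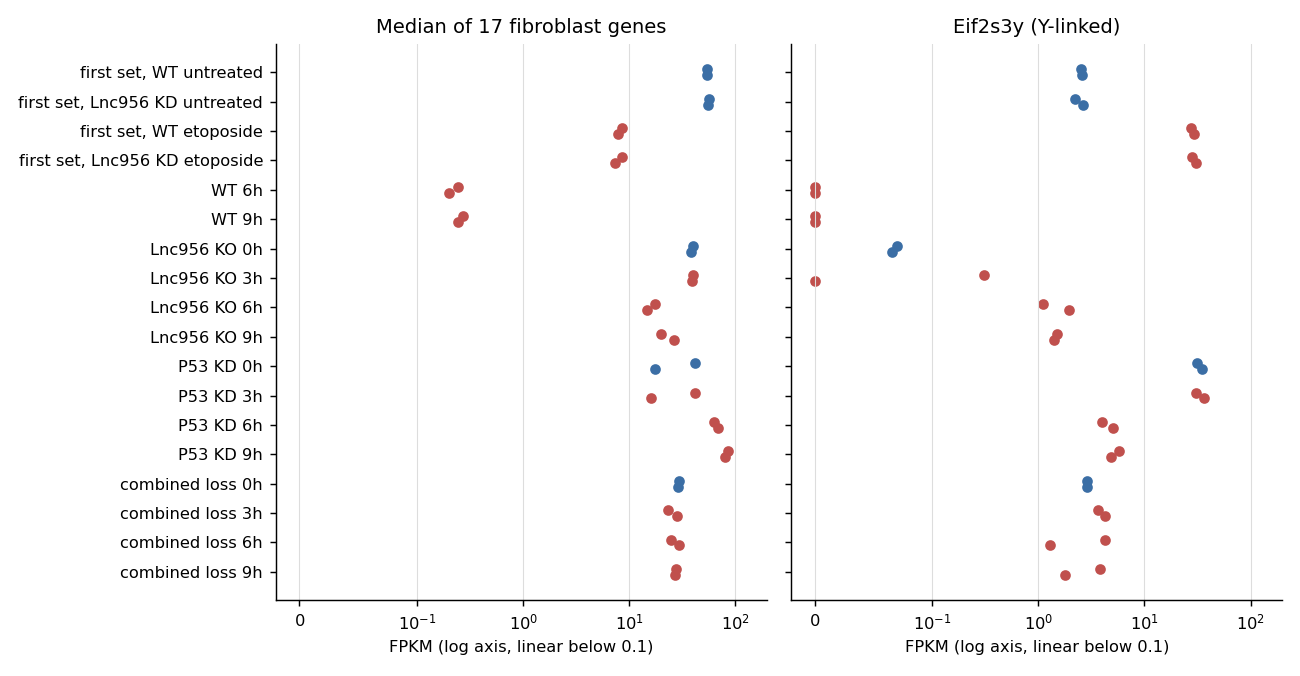
Median level of 17 fibroblast and feeder genes (left) and level of the Y-linked Eif2s3y (right) in FPKM (horizontal axes, log scale, linear below 0.1), with a point per RNA-seq library, a row per group and treated libraries in red. WT libraries of the time course lie lowest for fibroblast genes and at 0 for Eif2s3y, and knockout and P53 knockdown libraries of 0 h and 3 h lie apart from those of 6 h and 9 h.

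Comparisons 10 to 13 asked what Lnc956 loss adds when P53 is depleted, with combined-loss against P53 knockdown cells at 0 h, 3 h, 6 h and 9 h. As a list, naive genes stood higher in combined-loss cells from 3 h on, though Zfp42 did so already at 0 h. P53 targets were lower at 6 h and higher at 9 h. Zfp42 was 607 against 437 FPKM at 0 h, 604 against 226 FPKM at 3 h, 458 against 171 FPKM at 6 h and 317 ± 4.82 against 116 ± 4.95 FPKM at 9 h (SD, n = 2; log2 difference at 9 h 1.45 ± 0.09 SE, adjusted p = 6.72e-10). Esrrb did not pass at 0 h (adjusted p = 0.852) and was 77.4 against 32.4 FPKM at 3 h, 56.8 against 23.7 FPKM at 6 h and 31.4 against 14.8 FPKM at 9 h. Klf4 was 36.4 against 18.5 FPKM at 9 h. Mdm2 was 67.0 against 140 FPKM at 3 h and 57.5 against 97.8 FPKM at 6 h but 134 ± 5.74 against 76.0 ± 1.5 FPKM at 9 h (SD, n = 2; log2 difference 0.81 ± 0.10 SE, adjusted p = 4.89e-06), and Cdkn1a 348 against 192 FPKM at 9 h. Lefty1 and Lefty2, which encode antagonists of Nodal signalling, were lower in combined-loss cells. Lefty1 was at 6.24 against 90.4 FPKM at 6 h and 2.59 against 218 FPKM at 9 h. Lefty2 was at 0.991 against 68.1 FPKM at 9 h. Bnip3 and Egln3, both induced in low oxygen, were 16.7 against 164 FPKM and 3.64 against 64.2 FPKM at 9 h. Plaur, the urokinase receptor gene, was 349 against 34.7 FPKM and Chac1 91.2 against 8.96 FPKM at 9 h. Trp53 was also lower in combined-loss than in P53 knockdown cells at 0 h (56.9 against 106 FPKM).

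The numbers of genes that passed between combined-loss and P53 knockdown cells were 6388 at 0 h (3011 higher, 3377 lower), 6774 at 3 h (3026 higher, 3748 lower), 5298 at 6 h (2093 higher, 3205 lower) and 6819 at 9 h (2123 higher, 4696 lower). The 6 h count was 3429 without P53 knockdown replicate 2, 3396 without the libraries labelled 10 uM and 3230 in a fit with only the groups compared, where the 3 h count was 4453. At least 2-fold changes numbered 1337, 1407, 901 and 1535. Quantile scaling, which changed the log2 difference by 0.144 at 6 h and 0.215 at 9 h in the median over genes, gave 2682 higher and 2461 lower at 6 h and 3249 higher and 3131 lower at 9 h. No list passed at 0 h. Naive genes were 12 higher and 2 lower of 20 at 3 h (the same adjusted over the list alone, camera adjusted p = 0.00354), 14 and 2 at 6 h (14 and 3 adjusted over the list alone, 3.04e-06) and 13 and 4 at 9 h (the same adjusted over the list alone, 7.46e-04). G2/M genes were 8 higher and 0 lower of 17 at 3 h (0.00785) and 10 and 1 at 6 h (1.56e-05), with the same counts adjusted over the list alone. P53 targets were 5 higher and 22 lower of 32 at 6 h (camera adjusted p = 6.07e-04) and 13 higher and 6 lower at 9 h (0.00323), again the same adjusted over the list alone. Trophectoderm genes were higher at 3 h (7 and 1 of 9, camera adjusted p = 0.00785), and immediate early (9 and 2 of 14) and G1/S genes (10 and 4 of 19) at 9 h (0.00181 for each). Mesoderm (6 lower of 7, 0.0422) and neural genes (5 lower of 7, 0.0402) were lower at 9 h. Fibroblast genes were lower at 6 h (13 of 17, 2.01e-04) and 9 h (14 of 17, 0.00181). With an estimated correlation none passed (adjusted p from 0.146 to 0.617). Fibroblast levels in combined-loss cells were 29.3, 25.7, 26.9 and 27.2 FPKM at the successive times, against 29.7, 29.0, 66.0 and 82.8 FPKM in P53 knockdown cells, and Eif2s3y was 2.88, 3.96, 2.77 and 2.81 against 33.0, 33.4, 4.49 and 5.33 FPKM. P53 knockdown libraries thus changed in both markers between 3 h and 6 h, and combined-loss libraries did not. The 2 lines differed most in Eif2s3y at 0 h and 3 h and in fibroblast levels at 6 h and 9 h. The counts at each time, and shifts between 3 h and 6 h, may therefore in part measure such differences.

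Comparisons 14 to 16 asked how each cell line changed from 0 h to 9 h of etoposide. In combined-loss cells, whose marker levels stayed even, P53 targets rose and naive, general pluripotency and G2/M genes fell. Btg2 rose from 12.1 ± 2.21 to 82.9 ± 6.50 FPKM (SD, n = 2; log2 change 2.69 ± 0.17 SE, adjusted p = 1.32e-08), Cdkn1a from 123 to 348 FPKM, Mdm2 from 65.0 to 134 FPKM, Bbc3, which encodes the death factor Puma, from 12 to 45.3 FPKM and Phlda3 from 81.1 to 247 FPKM. Zfp42 fell from 607 to 317 FPKM, Esrrb from 71.0 ± 1.86 to 31.4 ± 0.465 FPKM (SD, n = 2; log2 change -1.15 ± 0.12 SE, adjusted p = 3.26e-06), Nanog from 265 to 182 FPKM and Klf5, another Kruppel-like factor of naive cells, from 188 to 86.7 FPKM. Klf4 did not pass (38.9 to 36.4 FPKM, adjusted p = 0.769). Several genes that fell most span long stretches of the genome, among them Kat6b (13.6 to 3.04 FPKM), Jmjd1c (16.8 to 4.80 FPKM) and Jarid2 (45.5 to 14.3 FPKM), while Plk1 fell from 86.6 to 27.3 FPKM. In all, 800 genes passed (345 higher, 455 lower), 121 of them at least 2-fold, and without single libraries the count lay from 317 to 439. Without the libraries labelled 10 uM, which include 1 of the 9 h libraries, it was 249. P53 targets were 19 higher of 32 (25 adjusted over the list alone, camera adjusted p = 4.93e-22), naive genes 8 lower of 20 (13 adjusted over the list alone, 3.41e-14), general pluripotency genes 6 lower of 15 (8 adjusted over the list alone, 3.46e-10) and G2/M genes 6 lower of 17 (10 adjusted over the list alone, 5.32e-12), and these 4 calls held with an estimated correlation. G1/S genes (2 higher, 3 adjusted over the list alone, camera adjusted p = 0.00176) and immediate early genes (2 higher, 4 with 1 lower adjusted over the list alone, 0.00901) passed with the preset correlation only (adjusted p = 0.476 with an estimated correlation for each).

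In knockout cells P53 targets rose and naive genes fell from 0 h to 9 h, and genes of the 2-cell stage rose. Mdm2 rose from 42.9 to 129 FPKM, Perp from 20.8 to 147 FPKM and Pmaip1 from 19.6 to 177 FPKM. Esrrb fell from 114 to 18.9 FPKM, Nanog from 223 to 106 FPKM and the G2/M kinase gene Plk1 from 123 to 15.6 FPKM. The 2-cell factor gene Dux rose from 0.644 to 3.97 FPKM. In knockout cells 9050 genes passed (6148 higher, 2902 lower), 3516 at least 2-fold. P53 targets were 25 higher and 4 lower (camera adjusted p = 1.96e-04), 2-cell genes 15 higher of 16 (7.64e-04), and naive genes 1 higher and 16 lower of 20 (5.49e-09). General pluripotency genes were 2 and 11 of 15 and G2/M genes 4 and 11 of 17 (1.96e-04 for each), interferon genes 2 and 8 of 13 (0.00574), G1/S genes 5 and 10 of 19 (0.0101) and formative genes 5 and 7 of 13 (0.0237). The naive call held with an estimated correlation and the others did not (adjusted p from 0.171 to 0.627). In P53 knockdown cells Lefty1 rose from 8.85 to 218 FPKM, Egln3 from 4.72 to 64.2 FPKM and Pmaip1 from 13.3 to 67.2 FPKM. Zfp42 fell from 437 to 116 FPKM and Esrrb from 73.1 to 14.8 FPKM, and Mdm2 did not pass (80.4 to 76.0 FPKM, adjusted p = 0.521). There 8568 genes passed (5593 higher, 2975 lower), 2777 at least 2-fold. P53 targets were 22 higher and 3 lower (camera adjusted p = 0.0036), naive genes 2 higher and 15 lower (3.06e-07), G2/M genes 2 and 11 and general pluripotency genes 2 and 10 (0.00128 for each) and fibroblast genes 11 higher (0.0251). None passed there with an estimated correlation (adjusted p from 0.0912 to 0.852). Quantile scaling gave 4158 higher and 4278 lower in knockout and 4181 higher and 4244 lower in P53 knockdown cells, with a median over genes of -0.383 and -0.163 for the change it made to the log2 values. These counts span a break in the series, since in knockout and P53 knockdown cells the Y-linked Eif2s3y went from 0.068, 0.154 and 33.0, 33.4 FPKM at 0 h and 3 h to 1.52, 1.45 and 4.49, 5.33 FPKM at 6 h and 9 h. With 6 h in place of 0 h the counts were 4148 in knockout and 1159 in P53 knockdown cells.

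**Figure D3:**
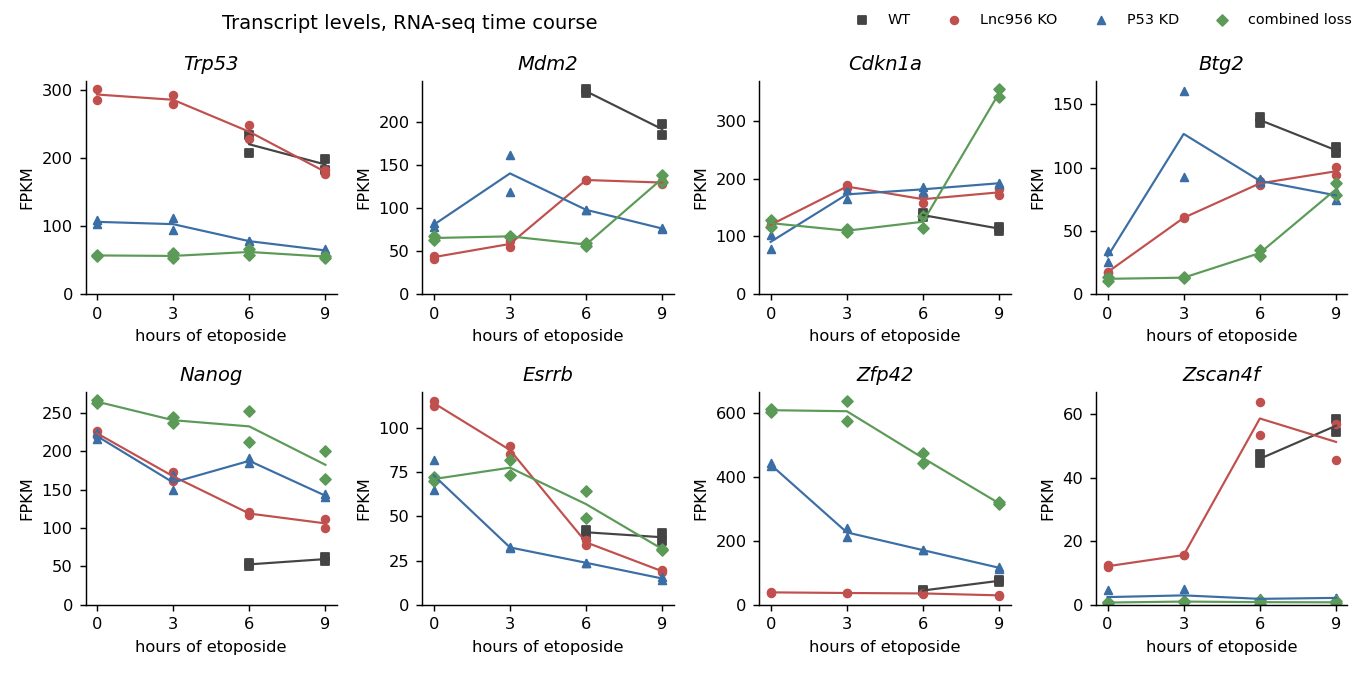
FPKM of named genes in the time course (vertical axis) by hours of etoposide (horizontal axis) for WT, knockout, P53 knockdown and combined-loss cells, with a point per library and lines through the means of n = 2. Zfp42 stood higher in combined-loss than in P53 knockdown cells at every time, also before etoposide, and Esrrb from 3 h on. Mdm2 crossed from lower at 6 h to higher at 9 h.

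The last comparisons across genes asked whether the 9 h response of combined-loss cells differed from that of each single loss. Against P53 knockdown cells, the response of Lefty1 differed by -4.50, that of Egln3 by -3.37, that of Esrrb by 1.07, that of Zfp42 by 0.97 and that of Mdm2 by 1.11 on the log2 scale (limma adjusted p = 1.83e-05 for Mdm2), while Nanog did not pass (adjusted p = 0.69). Against knockout cells, that of the interferon-induced peptide transporter gene Tap1 differed by -3.58, that of Pmaip1 by -2.45, that of Lin28a by 2.45, that of Esrrb by 1.38 and that of Mdm2 by -0.54. In all, 4861 genes passed against P53 knockdown cells (1674 higher, 3187 lower) and 6744 against knockout cells (2202 higher, 4542 lower), with 1840 and 3076 of at least 2-fold. The shares that were higher were 34.4% and 32.7%, against 50.3% and 52.4% after quantile scaling, which changed the log2 differences by 0.142 and 0.348 in the median over genes. Naive genes fell less in combined-loss cells than in P53 knockdown (10 higher and 3 lower, 11 and 3 adjusted over the list alone, camera adjusted p = 8.74e-04) and knockout cells (11 and 3, 4.43e-04). Against P53 knockdown cells fibroblast genes were lower (9 of 17, 0.0146) and immediate early genes higher (5 and 1 of 14, 0.00827). Against knockout cells 2-cell genes were lower (14 of 16, 6.28e-04). Interferon (8 and 1 of 13, 0.00643), G1/S (11 and 4 of 19, 4.43e-04) and formative genes (6 and 3 of 13, 0.0446) were higher, and G2/M genes passed as higher (8 and 4 of 17, 0.0369) with a median of 0.43 and a mean of -0.03. With an estimated correlation none passed (adjusted p from 0.533 to 0.734). With 6 h in place of 0 h 529 and 2121 genes passed. The 0 h and 9 h libraries of P53 knockdown and knockout cells lie on either side of the break in Eif2s3y and fibroblast levels, which combined-loss cells do not have.

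Lnc956 loss was measured in separate backgrounds, so its effects were also set side by side across genes, which are not independent replicates. At 6 h the knockout effect in P53-intact cells and that in P53 knockdown cells had a Pearson r of 0.026 (Spearman rho = 0.086). There 693 genes were higher in both against 457.1 if independent, 1105 were lower in both against 846.8, and of 2979 genes that passed in both 1181 went opposite ways. At 9 h r was -0.196 (rho = -0.129), with 398 genes higher in both against 497.7 if independent, 914 lower in both against 969.0, and 2090 of 3402 opposite. Fibroblast medians at 9 h were 23.1 FPKM in knockout against 0.258 FPKM in WT cells. They were 27.2 FPKM in combined-loss against 82.8 FPKM in P53 knockdown cells. Such opposite marker differences enter these values, so they do not show whether the effect of Lnc956 loss depends on P53. The treated knockdown effect of the first set went with the knockout effect at 6 h (r = 0.426, rho = 0.452, 1163 genes higher in both against 641.1 if independent, 1748 lower in both against 775.2) and not with that at 9 h (r = 0.0, rho = -0.026, 590 genes higher in both against 670.8 and 762 lower in both against 616.2). Nanog was higher and Mdm2 lower in both the knockdown and the knockout with P53 intact, while of these only the knockdown had higher Esrrb and Zfp42.

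Response to etoposide was also compared by the stretch of genome a gene spans, since topoisomerase II poisons can stall transcription along long genes such as Kat6b, Jmjd1c and Jarid2. In combined-loss cells at 9 h against 0 h the median log2 change of 1544 genes over 100 kb was lower than that of 6921 genes under 20 kb by -0.254 (bootstrap SE 0.007), and 10.1% of the long and 1.1% of the short genes passed as lower. In WT cells of the first set the median changes were -0.442 for 1418 long and 0.188 for 6016 short genes, and 66.4% and 26.6% passed as lower. The gap was -0.398 in knockdown cells of the first set, -0.108 in combined-loss cells at 6 h and -0.011 at 3 h. At 9 h against 0 h it was -0.043 in knockout and -0.734 in P53 knockdown cells, across the break in those lines. In WT cells it was -0.014 from 6 h to 9 h. Between combined-loss and P53 knockdown cells at 0 h, without etoposide, it was -0.312. Treated and untreated libraries of the first set were not alike in cell markers, which may enter their gaps.

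**Figure D4:**
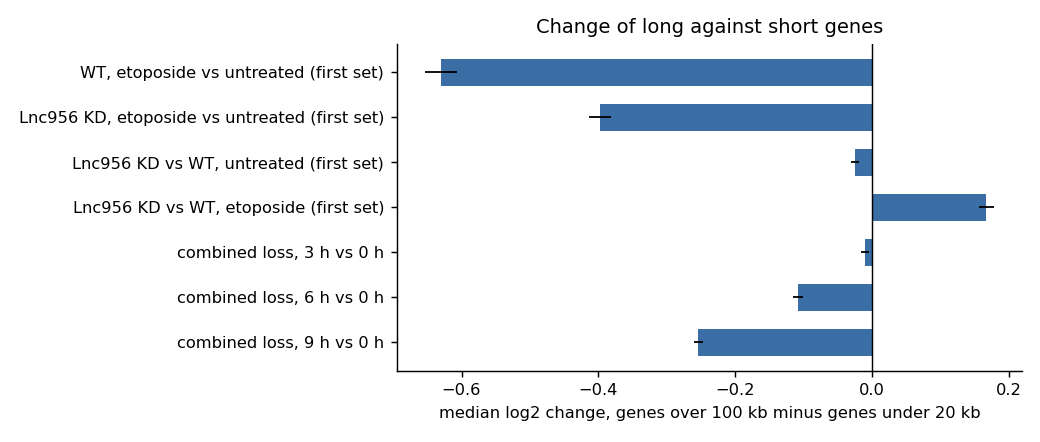
Median log2 change of genes that span over 100 kb minus that of genes under 20 kb (horizontal axis) for 7 comparisons of the first set and of combined-loss cells, with error bars for the bootstrap SE across genes. The difference was -0.254 in combined-loss cells at 9 h and -0.63 in WT cells of the first set.

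The P53 ChIP comparisons asked where P53 phosphorylated at serine 15 sits before and after etoposide, and whether Lnc956 knockdown changes this. P53 sites appeared at its target genes on treatment in both cell lines. In treated WT cells a P53 site covered the Cdkn1a start region (17:29089468-29092379, fold enrichment 13.9). Mdm2 had a site at 10:117717525-117717928 (9.4) and Ccng1 at 11:40754786-40756349 (15.8), and none of these genes had a site in both untreated libraries. Of 32 P53 targets, 0 had a site within 10 kb in untreated and 23 in treated WT cells, and 1 and 25 in knockdown cells. Weaker sites lay near Nanog (fold enrichment 5.6), Esrrb (5.5) and Zfp42 (5.5) in treated WT cells. The peaks of highest fold, beside Gm45871 on chromosome 18, Gm10222 and Gm10925 on chromosome 1 and Tmem196 on chromosome 12, were there with and without treatment. Those on chromosomes 18 and 1 were also among the KLF4 peaks of highest fold in untreated WT cells (115.5 and 104.0). They were thus not particular to P53. WT libraries held 1348 ± 43.1 peaks untreated and 6364 ± 232 treated, and knockdown libraries 1078 ± 136 and 5644 ± 844 (SD, n = 2). The treated number was 4.97 times the untreated one (exact permutation p = 0.0556 within genotype, two-sided, the smallest this design allows). On the log2 scale that is 2.31, and 1.31 after pileups were thinned to a common background, since treated P53 libraries had a higher background pileup (0.974 to 1.075) than untreated ones (0.481 to 0.630). Treated knockdown against WT libraries differed by -0.181 on the log2 scale (exact permutation p = 0.667, where 2 against 2 cannot go below 0.333). Of 4681 sites in both treated WT libraries, 3341 overlapped a site of treated knockdown cells. Of genes within 10 kb of a P53 site 45.3% rose in treated WT cells of the first set, against 36.9% of genes with no site (Fisher's exact odds ratio 1.416, p = 6.76e-18), and 33.2% against 39.4% fell (Fisher's exact odds ratio 0.767, p = 1.98e-10). Peak numbers were not paired by replicate number, which is all that links libraries of different groups in the labels.

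The KLF4 ChIP comparisons asked whether KLF4, a factor that holds ES cells in the naive state, stays on its sites under etoposide, and whether that depends on Lnc956. Fewer pluripotency genes kept a KLF4 site in treated WT than in treated knockout cells. Within 10 kb of 15 general pluripotency genes, a KLF4 site in both libraries was seen at 13 genes in untreated and 6 in treated WT cells, at 15 and 11 with full-length rescue, at 15 and 15 in knockout cells, and at 14 and 15 with the deletion rescue. For 20 naive genes the numbers were 18 and 13 in WT, 19 and 15 with full-length rescue, 19 and 20 in knockout and 20 and 19 with the deletion rescue. For 32 P53 targets they were 29 and 16 in WT, 29 and 26 with full-length rescue, 29 and 28 in knockout and 30 and 30 with the deletion rescue. The loss in WT cells was thus not particular to pluripotency genes. The Pou5f1 site of highest fold went from 47.7 to 8.6 in WT cells and from 21.8 to 23.1 in knockout cells. Sox2 had a site (fold enrichment 8.1) in untreated and none in treated WT cells, and the site at Klf4 itself went from 21.6 to 8.6 in WT cells. The Nanog site at 6:122702298-122703211 was 18.2 untreated and 22.3 treated in WT cells. The peaks behind these folds differ in width between groups.

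The number of KLF4 peaks followed the same order. WT libraries held 28942 ± 2331 peaks untreated and 6317 ± 885 treated, knockout libraries 27752 ± 6773 and 21836 ± 723, full-length rescue libraries 27956 ± 385 and 14263 ± 443, and deletion rescue libraries 27927 ± 173 and 24509 ± 467 (SD, n = 2). Treated against untreated, within cell line, the number was 0.528 times as high (exact permutation p = 0.0015, two-sided). Among treated libraries, WT and full-length rescue held 0.409 times the peaks of knockout and deletion rescue (log2 difference -1.289, exact permutation p = 0.0286, the smallest that 4 against 4 allows), while untreated libraries differed by 0.041 (exact permutation p = 0.771). The 8 treated libraries are 2 replicates of each of 4 lines, so this p counts libraries, and as a contrast of 2 lines against 2 lines it could not go below 0.333. Without knockout replicate 1 or 2 the log2 difference was as large (-1.305 and -1.328) with an exact permutation p of 0.0571, and without deletion rescue replicate 1 or 2 it was -1.267 and -1.254 with an exact permutation p of 0.0857 over 35 splits. Without a WT or full-length rescue replicate, also over 35 splits, the exact permutation p stayed at 0.0286. The share of untreated sites still held was 26.7% and 22.5% in WT replicates, 49.5% and 47.8% with full-length rescue, 72.7% and 71.3% in knockout and 69.0% and 70.4% with the deletion rescue, a difference of -34.2 percentage points (exact permutation p = 0.0286 over libraries). Of the 2000 strongest sites 91.6% to 100% were kept in every cell line, with a difference of -3.45 points. Kept means only that a peak was still called there. At the strongest untreated WT sites with a peak in every library of a line, the fold enrichment changed with treatment. The median log2 change was -1.522 and -1.434 in WT replicates and -0.835 and -0.862 with full-length rescue. It was -0.447 and -0.179 in knockout and 0.023 and 0.058 with the deletion rescue. Of 22566 untreated WT sites 16283 were lost, and 7282 of these were kept in both knockout libraries. Of genes near KLF4 sites lost in WT cells 36.9% fell in treated WT cells of the first set, against 39.5% of the others (Fisher's exact odds ratio 0.895, p = 4.82e-03), but genes near kept KLF4 sites gave the same ratio (0.898, p = 3.57e-03). The first of these calls was lost with a -log10 q of at least 5 (Fisher's exact p = 0.247) and within 2 kb of either gene end (Fisher's exact p = 0.115). Of 4681 P53 sites of treated WT cells, 2956 and 2811 held a KLF4 peak in the untreated WT libraries. In the treated WT libraries 1871 and 1709 did. Peaks at P53 sites made up 9.58% and 10.25% of KLF4 peaks in untreated and 27.15% and 30.04% in treated WT libraries. The loss at P53 sites was thus smaller than that over all KLF4 peaks. In knockout libraries 73.4% and 66.6% of the P53 sites held a KLF4 peak untreated, and 61.6% and 60.7% treated. Treated KLF4 libraries are labelled 3 h, while the times of the P53 ChIP and of the first RNA-seq set are not given and may differ.

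**Figure D5:**
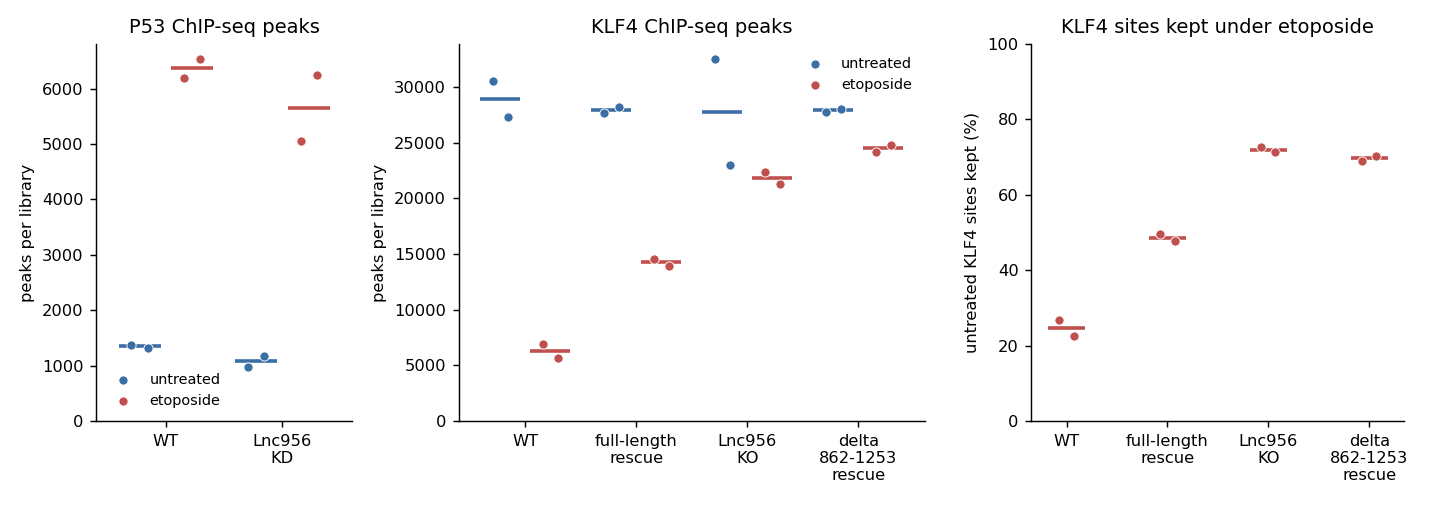
Number of P53 and KLF4 ChIP-seq peaks per library (left and middle, vertical axes) and percent of untreated KLF4 sites kept under etoposide (right) by cell line, with a point per library and a line at the mean of n = 2. P53 peaks rose with etoposide in both cell lines, and KLF4 peaks fell from 28942 to 6317 in WT but only to 21836 in knockout cells.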

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

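The tests of depth, of the deleted segment, of fibroblast share, of etoposide, of a separate batch and of other cells were chosen only after the result was seen, and both tests of immunoprecipitation yield before. Tests of differences between responses picked out 8 results. In the first set the etoposide response differed between Lnc956 knockdown and WT cells at 4212 genes. In the time course the 9 h response of combined-loss cells differed from that of P53 knockdown cells at 4861 genes and from that of knockout cells at 6744 genes, and with 6 h as the reference these numbers were 529 and 2121. The effect of the knockout differed between cells with and without P53 knockdown at 6869 genes at 9 h and 5885 genes at 6 h. These 2 counts rest on the WT libraries of the time course, whose cells differed in marker levels from the other lines. Their fibroblast median was 0.221 FPKM at 6 h and 0.258 FPKM at 9 h, against 16.1 and 23.1 FPKM in knockout cells. The counts may in part measure that difference. The share of KLF4 sites kept under etoposide differed by -34.2 percentage points between WT with full-length rescue and knockout with deletion rescue. Nanog, Mdm2, Esrrb, Lefty1 and Lin28a were among those whose responses differed.

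KLF4 peaks fell further under etoposide in WT and full-length rescue cells than in knockout and deletion rescue cells, as at Pou5f1 and Sox2. A difference in depth is argued against, since the log2 difference of peak numbers was still -1.27 after pileups were thinned to a common background. A gap of 19.5 percentage points parted the lowest share of sites kept in knockout and deletion rescue from the highest in WT and full-length rescue, which restates the pattern in the same libraries and so does not test whether Lnc956 with its deleted segment is the cause. That and a lower yield of the immunoprecipitation in the cells that lost peaks cannot be told apart. Departures of single sites from a common factor repeated between replicates in every cell line, by 0.06 more in WT than in knockout cells, and the departures of WT from knockout cells repeated less well than those of the deletion rescue from knockout cells, by -0.083, so both tests were saturated. A yield that was lower by cell line could therefore explain part of the loss, and the design holds no spike-in that would settle it.

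Fibroblast genes such as Dcn and Col3a1 were lower in treated than untreated libraries of the first set, in either genotype. A lower share of fibroblast RNA alone is argued against, since it would give 1 ratio at all genes, and the log2 ratios of 14 members with under 2 FPKM in WT cells of the time course ranged over 3.63, from Fbn1 (-0.54), Tagln (-0.83) and Acta2 (-1.18) to Dcn (-4.05), Postn (-4.05) and Col3a1 (-4.17). Etoposide itself may have lowered part of them and stays open: in combined-loss cells the list's median change from 0 h to 9 h was -0.002, but only 1 of the treated libraries there is labelled 10 uM. Its list median was 26.8 FPKM, against 27.5 FPKM in its replicate at 1 uM and 29.7 and 29.0 FPKM at 0 h, and a single library does not settle it. Eif2s3y was higher in the treated libraries of both genotypes (28.3 and 29.1 against 2.55 and 2.41 FPKM), while Eif2s3x lay from 90.7 to 96.7 FPKM in all 4 groups. The contrast of knockdown and WT cells within a treatment is alike in the fibroblast median and Eif2s3y, though the median of 4 Y-linked genes was 6.06 against 4.16 FPKM in treated cells, and that of treated and untreated cells is not alike.

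Knockout and P53 knockdown libraries of 0 h and 3 h stood apart from those of 6 h and 9 h, in Y-linked genes such as Eif2s3y, in the median of fibroblast genes and in pseudogenes. Whether etoposide acting between 3 h and 6 h caused this stays open. The median change of 4 Y-linked genes was -1.95 in P53 knockdown cells from 0 h to 6 h. It was 1.53 in treated against untreated WT cells of the first set. The opposite signs do not decide it, since those treated and untreated libraries were not alike in cell markers and their dose was mostly another. All 8 libraries of this block (8 of 8) lay above the 20 others of the time course in the share of FPKM from pseudogenes (1.57% to 1.75% against 1.19% to 1.43%), which is part of the pattern and so no test of a separate library or sequencing batch, which stays open. Whether other cells of the same label were harvested at 6 h and 9 h cannot be told apart from such a batch either, because both split the libraries alike. The Y-linked median of knockout cells changed by 0.52 on the scale of log2(FPKM + 1), which decides nothing, since the levels lay near 0 (0.054 FPKM at 0 h and 0.546 FPKM at 6 h), where the pseudocount compresses changes. Combined-loss cells, with Y-linked changes of -0.09 at 6 h and -0.02 at 9 h, had no such break, so the 9 h responses of knockout and P53 knockdown cells may in part measure it.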

How the results depend on the processing

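Thinned pileups, 2 kb of either gene end, leaving out the knockout and P53 knockdown libraries of 0 h and 3 h, 6 h as the reference and the crossed block were chosen only after the results were seen, and the other alternatives were planned. Over all results and alternatives 462 values stayed on their side of the threshold or, for counts, within 1.5 times the main count, 37 moved further and 6 lost their call. No called difference of single values changed sign. The untreated KLF4 difference (0.041), which did not pass, was -0.054 with -log10 q of at least 5 and -0.048 without knockout replicate 2. Quantile scaling turned the excess of higher or lower genes in 13 of the 18 comparisons (all but etoposide in knockdown cells, knockdown against WT untreated, knockout against WT at 6 h, combined-loss against P53 knockdown at 3 h and combined-loss cells from 0 h to 9 h), and so did a minimum log2 change of 1 for knockdown against WT untreated and the removal of 1 library for etoposide in WT cells, knockdown against WT treated and combined-loss against P53 knockdown at 0 h. The planned sites within 2 kb of gene starts were not run, since the reference gives no strand, and 2 kb of either end took their place. Depth is unknown and limits which genes near 1 FPKM and which weak peaks pass, and with 2 libraries per group a lone library left after a removal was assumed to vary like the other groups.

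A minimum log2 change of 1 lowered every count by construction: to 1977 and 1133 for etoposide in WT and knockdown cells, 89 and 441 for knockdown against WT untreated and treated, 443 for the difference of responses, 2118 and 1730 for knockout and 2710 and 2686 for P53 knockdown against WT at 6 h and 9 h, 1337, 1407, 901 and 1535 for combined-loss against P53 knockdown cells from 0 h to 9 h, 3516, 2777 and 121 for 9 h against 0 h in knockout, P53 knockdown and combined-loss cells, and 1840 and 3076 for the differences of combined-loss from P53 knockdown and knockout responses. With only the groups compared, combined-loss against P53 knockdown gave 4453 genes at 3 h and 3230 at 6 h, with fewer libraries behind the variance. Without the 10 uM libraries it gave 3396 at 6 h, and combined-loss cells at 9 h against 0 h gave 249, with fewer libraries. With 6 h as the reference the counts were 4148 for knockout and 1159 for P53 knockdown cells, and 529 and 2121 for the differences of combined-loss from P53 knockdown and knockout responses, where the first 6 h of the response are left out by construction. With an estimated correlation 7 calls of gene lists passed in place of 87. KLF4 sites lost in WT near genes that fell had an odds ratio of 0.956 (Fisher's exact p = 0.247) with -log10 q of at least 5 and 0.944 (p = 0.115) within 2 kb of either end, and the cause was not tested.

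Leaving out each library in turn gave 8838 to 8965 and 7644 to 7979 genes for etoposide in WT and knockdown cells, 869 to 2313 and 4413 to 4890 for knockdown against WT untreated and treated, and 3048 to 3610 for the difference of responses. Knockout against WT gave 5420 to 5781 at 6 h and 4616 to 5023 at 9 h, and P53 knockdown against WT 6156 to 6247 and 6219 to 6522. Combined-loss against P53 knockdown gave 4368 to 5947 at 0 h, 5110 to 6153 at 3 h, 3429 to 5336 at 6 h (3429 without P53 knockdown 6 h replicate 2) and 5034 to 5443 at 9 h. From 0 h to 9 h the counts were 7758 to 8062 in knockout, 7000 to 8007 in P53 knockdown and 317 to 439 in combined-loss cells (439 and 317 without 0 h replicate 1 and 2, 424 and 366 without 9 h replicate 1 and 2), and the differences of responses 3549 to 4995 and 5448 to 6218. Knockdown against WT untreated gave 1119 and 1434 without WT replicate 1 and 2 and 869 without knockdown replicate 1. The treated KLF4 difference was -1.496 to -1.044, and lost its call without knockout replicate 1 or 2 (-1.305 and -1.328, exact permutation p = 0.0571) and without deletion rescue replicate 1 or 2 (-1.267 and -1.254, exact permutation p = 0.0857), and the cause was not tested. The untreated difference was -0.048 to 0.119, treated against untreated KLF4 -0.984 to -0.858, kept sites -38.533 to -29.535 points, P53 treated against untreated 2.236 to 2.389 and P53 knockdown-line against WT -0.334 to -0.028.

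Replicates share only a number, so a replicate block was tried as an alternative to the unpaired fit. With the block the counts were 9709, 8656, 2812, 5672 and 4035 in the first set in the order of the report, 6839 and 6247 for knockout and 7557 and 7723 for P53 knockdown against WT, 6372, 6736, 5280 and 6796 for combined-loss against P53 knockdown cells, 9039, 8575 and 748 from 0 h to 9 h, and 4848 and 6758 for the differences of responses. Replicates of the same number did not pair better than others in every comparison, since the correlation of their departures ranged from -0.297 to 0.275. With crossed numbers the counts were 9755 for etoposide in WT cells, 6823 and 6275 for knockout against WT at 6 h and 9 h, 6874 for combined-loss against P53 knockdown at 9 h and 795 for combined-loss cells from 0 h to 9 h.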

Other observations

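The tests of long genes in combined-loss and knockdown cells and of a list of low-oxygen transcripts were chosen after the genes that prompted them were seen but before the tested values were, and the test of genes near kept KLF4 sites only after. Changes from 0 h to 3 h and from 6 h to 9 h, which the report does not give, were fitted in the same models. P53 targets already rose at 3 h in P53 knockdown cells, which keep part of their Trp53 transcript: 15 of 32 rose (23 adjusted over the list alone, camera adjusted p = 2.64e-16), and this held with an estimated correlation. In knockout cells 4 rose at 3 h (10 adjusted over the list alone, camera adjusted p = 1.32e-08 with the preset correlation). In combined-loss cells 0 genes passed at 3 h by limma, with 454 at an unadjusted p under 0.05. From 6 h to 9 h 22 P53 targets rose and 1 fell in combined-loss cells (25 and 2 adjusted over the list alone, camera adjusted p = 4.41e-18 with the preset correlation). The numbers of genes that passed at 3 h were 64 in knockout and 737 in P53 knockdown cells, and from 6 h to 9 h 1719 in WT, 4148 in knockout, 1159 in P53 knockdown and 1649 in combined-loss cells. The P53 knockdown replicates at 3 h differed from each other in Mdm2 (SD 30.8 around 140 FPKM) and Btg2 (SD 48.5 around 127 FPKM).

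Several genes that fell most in combined-loss cells, such as Kat6b, Jmjd1c and Jarid2, span long stretches of the genome, and the hypothesis that etoposide lowers transcripts of long genes was tested. The median change of genes over 100 kb minus that of genes under 20 kb was -0.254 at 9 h, beyond the bound set before, and grew from -0.011 at 3 h and -0.108 at 6 h. Between combined-loss and P53 knockdown cells at 0 h, without etoposide, the gap was -0.312 (SE 0.02), larger than that change. Between the same lines it was 0.129 at 6 h and 0.109 at 9 h, after the break in P53 knockdown cells. From 6 h to 9 h the gap was -0.014 in WT, -0.113 in knockout, -0.174 in P53 knockdown and -0.13 in combined-loss cells. A gap of this size thus also lay between libraries without the drug, but that break may enter it. The genes were not independent, and the cause stays open. In knockout cells the gap at 9 h was -0.043 and in P53 knockdown cells -0.734, where the break between 3 h and 6 h also enters. Among genes with a mean of 10 FPKM or more it was -0.354 and -1.036 there and -0.364 in combined-loss cells.

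Genes such as Jarid2, Ctbp2 and Etl4 were higher in treated knockdown than treated WT cells, and a smaller effect of etoposide on long genes in knockdown cells was tested. The gap between long and short genes was 0.167 (untreated -0.025), between the bounds set before for presence and absence, and 0.276 among genes with a mean of 10 FPKM or more. Whether long genes were spared in knockdown cells therefore stays open, because the value fell between those bounds.

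Ndrg1, Bnip3 and Adm were lower in untreated knockdown cells, and a list of 26 other genes induced in low oxygen was tested as a set. Its median change was -0.82, with 0 members higher and 23 lower, and 0 of 10000 random lists matched on expression lay as low. The list moved in many other contrasts too: by -1.041 with etoposide in WT cells (24 of 26 lower), by -0.23 in treated knockdown against treated WT cells, by 0.596 in the difference of responses, and by 1.27 and 1.72 in P53 knockdown against WT cells at 6 h and 9 h. The count of genes between untreated knockdown and WT cells also fell from 3032 to 869 without knockdown replicate 1. The cause stays open, because culture density was not tested. The list's median was also lower in combined-loss than in P53 knockdown cells at 6 h (-1.082) and 9 h (-1.239) and less so at 0 h (-0.204). There it was P53 knockdown cells that rose, by 0.827 from 0 h to 6 h and 1.19 from 0 h to 9 h across the break in that line, against -0.003 and 0.14 in combined-loss cells. The median was 0.019 and 0.783 between knockout and WT cells at 6 h and 9 h.

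Kept KLF4 sites might hold up transcripts of genes nearby, which was tested with the difference of treated knockdown and WT cells. Genes near sites lost in WT and kept in knockout cells exceeded genes with no site by 0.037 in the median. This lay under the bound of 0.1. The 5974 genes near sites lost and kept in this way went both ways. In treated knockdown against treated WT cells 1482 of them were higher and 1417 lower. A median over genes that go both ways does not show whether some of them rose, so the test draws no conclusion. KLF4 was profiled in knockout cells at 3 h, and the transcripts were measured in knockdown cells at a time not given. This compares different lines and perhaps different times, so it does not decide whether kept sites hold up transcripts nearby.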
